A study of Homo sapiens with 6 samples.

How the data were processed

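The data are bulk RNA-sequencing libraries of HaCaT cells, a spontaneously immortalized line of human epidermal keratinocytes. There were 2 groups of 3 libraries, wild-type control cells and cells labelled as a homozygous SDR42E1 knockout, made by CRISPR editing. Per the labels' protocols, total RNA was extracted from subconfluent monolayers and made into stranded total-RNA libraries. The labels call the replicates biological and do not say whether they were separate cultures or separate edited clones, so the p-values measure the spread between these libraries.

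The authors deposited 1 table of raw read counts per gene, with 1 column per library. The genome build was GRCh38, per the submitters' processing notes; the aligner, the counting tool and its strand setting are not given in the sources used here. The table held 46287 rows, 31254 named by symbol and 15033 by Ensembl identifier, and 16383 had a count in at least 1 library. All 6 columns were matched to samples by name, and 0 rows lacked a gene. Library totals ran from 11504473 to 16928201 counts. In each of the 6 pairs of libraries of 1 group the counts differed by more than sampling noise. Chi-square per degree of freedom was 2.65 to 4.49, over genes with a summed count of at least 20. This goes against repeated reads of 1 library but cannot show separate cultures. Each library was kept as a replicate, as the labels have it. In 8 genes or readthrough loci, EIF3CL and HSPE1-MOB4 among them, libraries of 1 group held both 0 and 100 or more counts, so the counting could have split reads between overlapping or near-identical genes unevenly. Members of near-identical pairs and families (ALPP and ALPG, KRT6A, KRT6B and KRT6C, SERPINB3 and SERPINB4, AKR1C1, AKR1C2 and AKR1C3) are uncertain for that reason.

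Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries scaled by TMM, and knockout compared with control by the robust quasi-likelihood F test over all 6 libraries, with no block. The test is two-sided, and p was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The same test gave every adjusted p printed for a gene. Fold changes are log2 of knockout over control (prior count 0.125), the SE is the absolute log2 fold change over the square root of F, and CPM values, computed from the deposited counts, are scaled to the TMM-adjusted library size and given as mean ± SD with n = 3. On counts simulated from these libraries over 12250 genes, 50 genes changed at each fold size, edgeR recovered 40% of those changed 1.25-fold, 78% at 1.5-fold, 86% at 2-fold and 96% at 4-fold, with 9 calls among unchanged genes.

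Before the data were examined, 33 gene lists holding 650 different genes were fixed from general knowledge of keratinocyte biology, sterol and vitamin D metabolism, stress and signalling responses, cell division, other cell types and mitochondrially encoded RNA. Each was tested with camera in limma 3.58.1 on voom-weighted log2 CPM with an inter-gene correlation preset at 0.01, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The former takes its p from the few residual degrees of freedom of 6 libraries, the preset form from the number of genes. The named genes were fixed by rule at the same time: SDR42E1; the 12 largest rises and 12 largest falls among genes past the threshold with a mean log2 CPM of at least 2, a symbol and no overlap between the groups; and from each list described, up to 4 members with the smallest adjusted p. Further members are named in places, and these were chosen after their values were seen. Some list members are not reported here by name.

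The other settings, listed before the data were examined, were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, and leaving out each library. Gene positions came from GENCODE release 29 on GRCh38. Positions along chromosomes were looked at only after the gene results: log2 fold changes of 10364 genes with a mean log2 CPM of at least 2 were divided by circular binary segmentation on ranks, with at least 15 genes per segment and 1000 permutations per split at a p threshold of 0.001. Plain binary segmentation missed a planted stretch inside a chromosome and was replaced before its output on these data was seen. With gene positions shuffled the method made 0 splits. It placed the ends of a planted stretch of 60 genes with a shift of -0.5 to within 1 gene. Smaller shifts and shorter stretches were not planted, so the edges of such stretches are less certain. A segment with an absolute median of at least 0.2 is called a shifted stretch. DNA, protein and vitamin D levels were not analysed here.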

Results

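RNA was measured in 6 libraries of HaCaT keratinocytes, 3 from wild-type control cells and 3 from homozygous SDR42E1-knockout cells. SDR42E1 belongs to the short-chain dehydrogenase/reductase family, and the study asked how its loss changes the transcriptome, in connection with vitamin D. Control libraries held 13728748, 16928201 and 12094896 counts, and knockout libraries 11889804, 13454544 and 11504473. The 2 groups lay apart on the first principal component, which held 70.6% of the variance, and correlations of log2 CPM were 0.987 to 0.991 within a group and 0.959 to 0.963 between groups.

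SDR42E1 RNA was lower in every knockout library than in every control library, and was still present. Its level was 47.7 ± 1.02 CPM in control cells (650, 822 and 601 counts) and 21.3 ± 1.61 CPM in knockout cells (268, 265 and 237 counts; SD, n = 3 each). The log2 fold change was -1.16 (SE 0.08, adjusted p = 2.69e-14 in edgeR's quasi-likelihood test). The gene lies on the minus strand of chromosome 16, from 81988855 to 82011488 (GRCh38), and its full-length coding transcript has 3 exons. Its neighbours were lower too: the 55 tested genes between SDR42E1 and the end of the long arm, with a mean log2 CPM of at least 2, had a median log2 fold change of -0.75, and 55 of the 55 were below 0. SDR42E1 differed from that median by -0.41, where the SD among those genes was 0.37. The position of the edit is not given in the sources used here, and a gene-level count cannot show it.

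The 12 largest rises included 4 genes of interleukin-1 family ligands and receptors, IL1RL1, IL1A, IL1R2 and IL1B. IL1RL1, the receptor of interleukin-33, went from 0.513 ± 0.256 to 12.3 ± 1.71 CPM (log2 fold change 4.64, SE 0.27). IL1A, an alarmin cytokine of keratinocytes, rose 10.2-fold (log2 3.35, SE 0.14), IL1B 5.86-fold (log2 2.55, SE 0.08), and IL1R2, the decoy receptor of interleukin-1, 8.54-fold (log2 3.09, SE 0.25). SERPINB2, an inhibitor of plasminogen activators, reached 1090 ± 48.6 CPM from 120 ± 20.2 (log2 3.18, SE 0.14). AREG, an EGF receptor ligand, rose by 2.89 on the log2 scale (SE 0.09). TFPI2 (log2 3.17) is a protease inhibitor of the matrix and ANGPTL4 (log2 2.91) a secreted inhibitor of lipoprotein lipase. IGFL1 (log2 4.46), ANTXR2 (2.97), ADGRF4 (2.74) and PPP4R4 (2.64) complete the 12. These are the largest among genes with a mean log2 CPM of at least 2 and no overlap between the groups. Adjusted p for these rises was at most 2.63e-05, the value for SERPINB2.

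Several of the largest falls took genes to a few counts per library. PLXDC2, a transmembrane protein, had 649 counts over the control libraries and 2 over the knockout libraries, a ratio of 270 after scaling (95% counting interval 74.4 to 2233). DAPK1, a calmodulin-regulated kinase linked to cell death, fell from 38.2 ± 1.43 to 0.588 ± 0.329 CPM (log2 fold change -6.02, SE 0.18). HMCN1, an extracellular matrix protein, fell from 84.2 ± 3.37 to 3.40 ± 0.329 CPM (log2 -4.63, SE 0.11). FAT3, an atypical cadherin, changed by -4.70 (SE 0.17) and NTRK2, the receptor of brain-derived neurotrophic factor, by -4.21 (SE 0.22; -4.82 without knockout replicate 3). DHX58, a regulator of viral RNA sensing, changed by -4.64 (SE 0.24). DHX58 lies in a stretch of chromosome 17, and HMCN1 in one of chromosome 1, where most tested genes were lower in the knockout. ALPG (log2 -4.85), MPPED2 (-4.78), TRIM31 (-4.71), SAMD11 (-4.12), ANK1 (-3.70) and SH3BGRL (-3.48) were the others among the 12 largest falls with a mean log2 CPM of at least 2. Reads of ALPG may be split with its near-identical neighbour ALPP, which also fell (log2 -2.97).

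**Figure D1:**
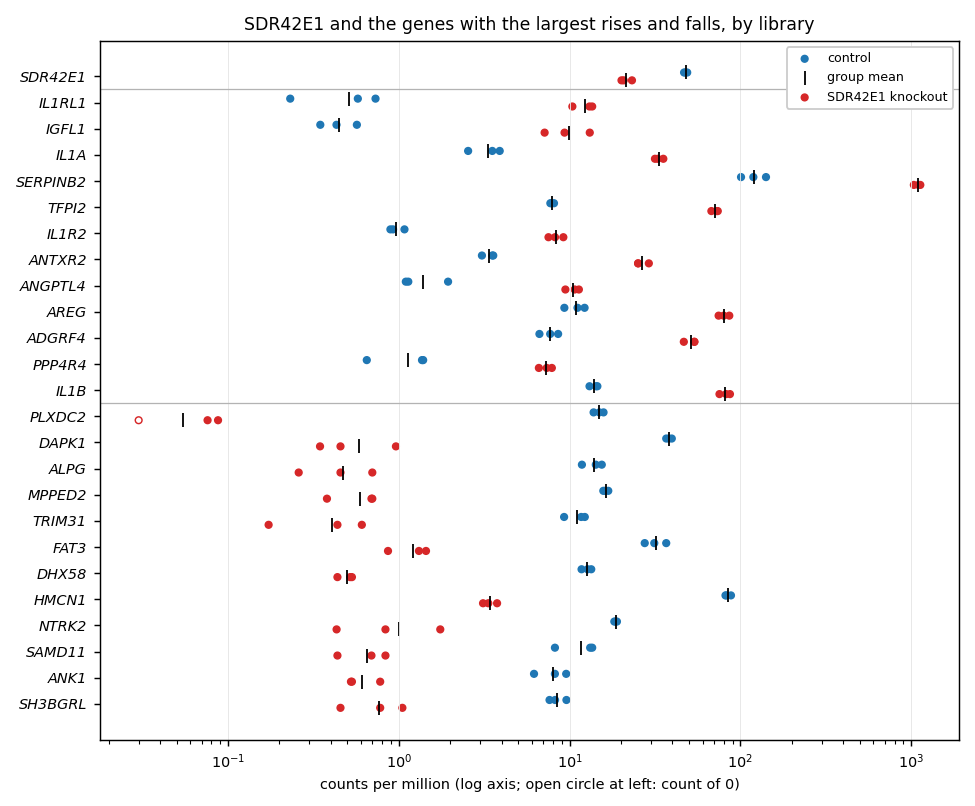
CPM (counts scaled to library size, log axis) of SDR42E1 and the 12 genes with the largest rises and the 12 with the largest falls, with 1 point per library (blue, control; red, knockout) and a black tick at each group mean. The rises and falls were chosen among genes with a mean log2 CPM of at least 2 and no overlap between the groups. The groups do not overlap for any of the 25 genes; SDR42E1 stays at 21.3 CPM in the knockout, while PLXDC2 falls to 2 counts over 3 libraries.

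Of 12293 genes tested, 6197 passed the threshold, 3022 higher and 3175 lower in the knockout. Changes of at least 2-fold were mostly falls, with 643 falls against 235 rises (878 in all). Without the genes of shifted stretches, an alternative chosen after seeing the data, 511 falls and 217 rises remained. Genes of low expression leaned downward in general. Of 1415 with a mean log2 CPM under 2 outside those stretches, 64.9% were below 0 (median -0.25). In 56.5% of tested genes the groups did not overlap, where chance gives 10%. The common biological coefficient of variation was 0.0539, so small changes passed the test and the counts describe differences between these particular cells.

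Genes of wounded and stressed keratinocytes rose as a group. Of 18 tested members, 14 rose, 1 fell and 3 did not pass (adjusted over the list alone, 15 rose and 1 fell), with a median log2 fold change of 1.16 and an adjusted camera p of 1.32e-08. Adjusted p = 0.181 with an estimated correlation. The EGF receptor ligand EREG rose by 2.07 (SE 0.07) beside AREG, and the wound keratins KRT6A and KRT17 by 1.26 and 0.66, although reads of KRT6A may be split among KRT6 genes and KRT17 lies in a shifted stretch of chromosome 17. LCN2, a neutrophil and keratinocyte antimicrobial protein, was the member that fell (log2 -3.23).

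The NF-kB and cytokine list had 12 members up, 3 down and 2 not past the threshold of 17 tested (13 up and 3 down adjusted over the list alone), with a median of 1.10 and an adjusted camera p of 0.000197. Adjusted p = 0.251 with an estimated correlation. Beside IL1A and IL1B, TNFAIP3, an inhibitor of NF-kB signalling, rose by 2.53 (SE 0.08) and the cytokine gene LIF by 1.96. The members that fell were TNFAIP2 (-0.86) and the chemokine genes CCL2 (-5.06, or -5.92 without knockout replicate 2) and CCL5 (-1.28), of which CCL2 and CCL5 lie in a shifted stretch of chromosome 17. The list of MAPK feedback and AP-1 genes had 14 up, 3 down and 2 not past the threshold of 19 (14 up and 4 down adjusted over the list alone), with a median of 0.63 and an adjusted camera p of 0.000106. Adjusted p = 0.181 with an estimated correlation. PHLDA1 rose by 1.92, the ERK phosphatase genes DUSP4 and DUSP6 by 1.82 and 1.01, and FOSL1, an AP-1 subunit, by 2.31 (SE 0.10). The 3 that fell were the AP-1 subunit genes FOS (-2.11), FOSB (-1.55) and JUNB (-0.48).

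Cholesterol biosynthesis genes rose together by smaller steps. Of 20 tested, 12 rose, 1 fell and 7 did not pass, also when adjusted over the list alone (median 0.26, adjusted p = 0.000239 by camera). Adjusted p = 0.204 with an estimated correlation. HMGCS1, an early enzyme of the mevalonate pathway, went from 63.2 ± 3.31 to 145 ± 14.5 CPM (log2 1.19, SE 0.06), and the later enzymes MSMO1, CYP51A1 and SQLE rose by 0.91, 0.62 and 0.68. MVD was the member that fell (log2 -0.81), and it lies between SDR42E1 and the end of chromosome 16. The list of sterol uptake and fatty acid genes regulated by SREBP had 11 up and 5 down of 20 (the same counts adjusted over the list alone, adjusted p = 0.130 by camera, or 0.556 with an estimated correlation). The sterol carrier gene STARD4 rose by 1.34 (SE 0.11), while SREBF1 and ACACA, both in a shifted stretch of chromosome 17, changed by -0.69 and -0.42.

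Genes of vitamin D metabolism and signalling moved both ways. Of 13 tested, 4 rose and 3 fell (4 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.898 by camera); its median was -0.01 and its mean 0.01, of opposite sign. The falls were the receptor partner RXRA (-0.68) and the coregulators MED1 (-0.91) and NCOR1 (-0.48), of which MED1 and NCOR1 lie in shifted stretches of chromosome 17. The rises were EBP (0.47, SE 0.05), a sterol isomerase, and DHCR7 (0.41), which turns the skin precursor of vitamin D into cholesterol. CYP27B1, which makes the active hormone, rose from 5.75 ± 0.457 to 12.1 ± 2.49 CPM (log2 1.07, SE 0.16), and CYP3A5, a broad steroid and drug hydroxylase, by 0.80. The receptor VDR had a log2 fold change of -0.01 (adjusted p = 0.961) and CYP24A1, the enzyme that breaks the hormone down, -0.38 (adjusted p = 0.106; -0.51 and 0.0473 without control replicate 2, -0.19 and 0.498 without control replicate 1). Targets of the receptor split into 4 that rose and 7 that fell of 16 (also adjusted over the list alone, adjusted p = 0.403 by camera), with SERPINB1 at 0.84, DUSP10, in the shifted stretch of chromosome 1, at -0.58, the calcium channel gene TRPV6 at -1.75 and the kallikrein gene KLK6 at -1.43. Steroid and short-chain dehydrogenase genes had 6 up and 10 down of 24 (7 and 10 adjusted over the list alone, adjusted p = 0.491 by camera); NSDHL rose by 0.62, HSD17B4 changed by -0.31 and STARD3, in a shifted stretch of chromosome 17, by -0.60.

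In the basal and hemidesmosome list 12 rose, 3 fell and 4 did not pass of 19 (13 and 3 adjusted over the list alone, median 0.32, adjusted p = 0.000447 by camera). Adjusted p = 0.182 with an estimated correlation. The laminin chain gene LAMA3 rose by 1.59 and the integrin gene ITGA3 by 0.65, whereas the basal keratin genes KRT5 and KRT15 changed by -0.66 and -1.83 and KRT14 had a value of -0.07 that did not pass; KRT14 and KRT15 lie in a shifted stretch of chromosome 17. In the early differentiation list 5 fell, 1 rose and 5 did not pass of 11 (the same adjusted over the list alone, median -0.13, adjusted p = 0.0204 by camera). Adjusted p = 0.231 with an estimated correlation. The falls were KRT4 (-2.95), KRT13 (-1.17), the receptor gene NOTCH3 (-3.95, or -4.61 without knockout replicate 3), CEBPA (-1.03) and KRT10 (-1.06). KRT10 and KRT13 lie in a shifted stretch of chromosome 17, and without the genes of shifted stretches, an alternative chosen after seeing the data, this list no longer passed (adjusted p = 0.0882 by camera).

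In the list of mitotic genes 14 fell, 2 rose and 4 did not pass of 20, also adjusted over the list alone (median -0.24, adjusted p = 0.000213 by camera). Adjusted p = 0.181 with an estimated correlation. TOP2A (-1.30), CENPF (-0.73), NUSAP1 (-0.54) and KIF20A (-0.55) had the smallest adjusted p; TOP2A and CENPF lie in shifted stretches, and the median without such genes was -0.15 (adjusted p = 0.00115 by camera). In the list of hypoxia and glycolysis genes 15 rose, 3 fell and 5 did not pass of 23 (15 and 4 adjusted over the list alone, median 0.24, adjusted p = 0.00137 by camera). Adjusted p = 0.251 with an estimated correlation. The hexokinase gene HK2 rose by 1.40, VEGFA by 0.91, ADM by 0.73 and LDHA by 0.45. Camera with an estimated correlation called 0 of the 33 lists (smallest adjusted p = 0.181), against 8 with the preset value. With 6 libraries the former has few degrees of freedom, so lists it did not call are not shown to be unchanged. Fry, which does not compare a list with other genes, called 26 in 1 direction.

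**Figure D2:**
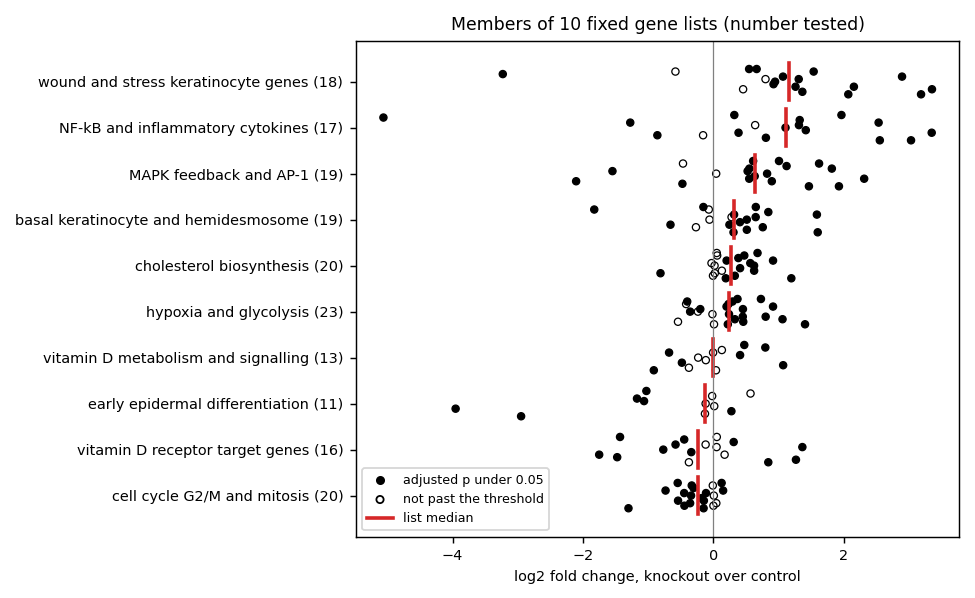
Log2 fold changes (knockout over control) of the tested members of 10 fixed lists, 1 point per gene, filled where the adjusted p of the gene is under 0.05, with the list median in red and the number tested in brackets. The wound list has its median at 1.16 and the mitotic list at -0.24, and both vitamin D lists have filled points on both sides of 0.

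Lower expression also followed chromosome position, a pattern found after the gene results were seen. On chromosome 16 the short arm had a median log2 fold change of 0.09 (257 genes), the long arm up to CMIP -0.31 (162 genes), and the stretch from PLCG2 to GAS8, at 81.7 to 90.0 Mb and including SDR42E1, -0.76 (57 genes, 95% bootstrap interval -0.88 to -0.64, 100% below 0). On chromosome 17 the median was -0.28 from 0.4 to 38.4 Mb (265 genes), -0.81 from 38.4 to 42.7 Mb (68 genes, interval -0.92 to -0.66), and 0.07 beyond. The latter stretch, from ARHGAP23 to EZH1, holds TOP2A, KRT10, KRT13, MED1 and DHX58. Chromosome 1 from 121.2 Mb to its end had a median of -0.30 (476 genes), and 25 genes of chromosome 19, at 51.3 to 53.4 Mb, -0.24. Smaller shifts lay under the limit of 0.2 that defines these stretches: chromosome 10 had a median of -0.18 over its whole length (390 genes, 75.1% below 0), chromosome 13 one of -0.12 (173 genes, 72.3% below 0) and chromosome 1 from 16.2 to 26.1 Mb one of -0.13 (70 genes). Upward shifts under the limit were 0.16 on chromosome X from 103.4 Mb to its end (123 genes, among them NSDHL), 0.13 on X from 43.7 to 49.3 Mb (43 genes, among them EBP) and 0.11 on chromosome 7 (490 genes). The 6 stretches held 25.3% of the genes that fell and 2.58% of those that rose, among 10.2% of tested genes with a position. The stretches were chosen on these same fold changes and all 6 were lower, so these shares describe the choice and test nothing.

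**Figure D3:**
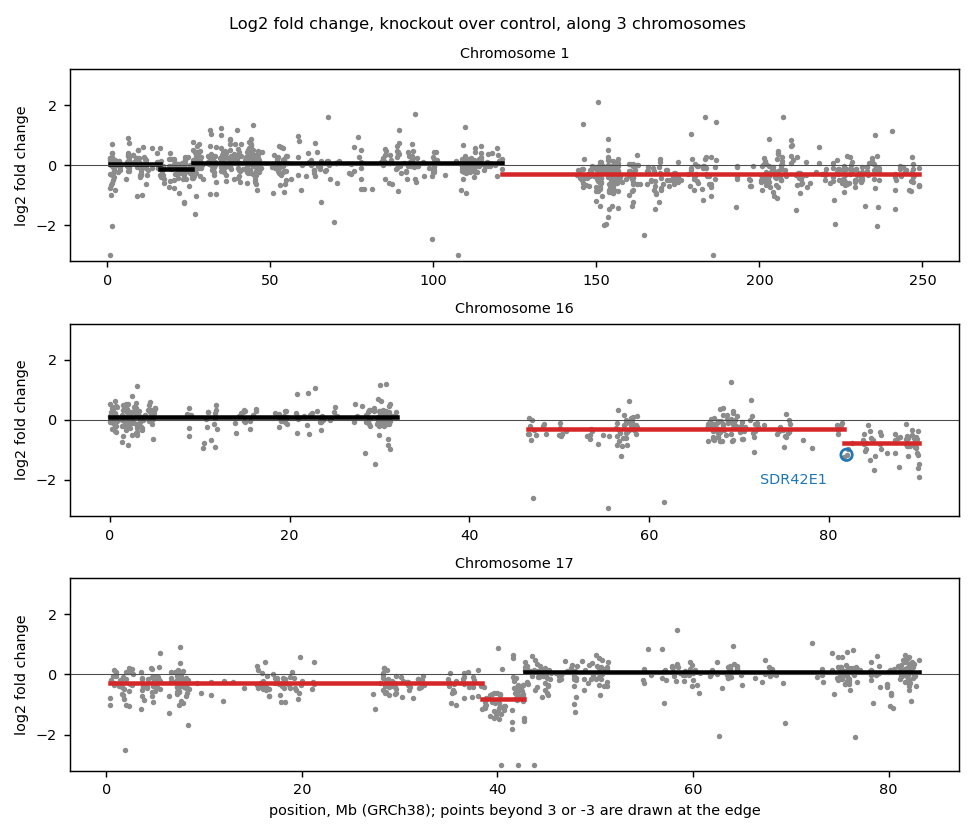
Log2 fold change (knockout over control) against position in Mb (GRCh38) for genes of chromosomes 1, 16 and 17 with a mean log2 CPM of at least 2, 1 grey point per gene, with bars at segment medians (red where the absolute median is at least 0.2) and SDR42E1 circled. On chromosome 16 the bars step from 0.09 to -0.31 and to -0.76, the last step lying beside SDR42E1.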

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

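The counts without genes of the shifted chromosome stretches were chosen after seeing the data; the other alternatives were planned. SDR42E1 stayed lower in the knockout and past the threshold under each planned setting, with log2 fold changes from -1.22 (without knockout replicate 1) to -1.12 (without knockout replicate 2). Against 6197 changed genes, DESeq2 called 5308, of which 5170 were shared with the edgeR result, RLE scaling 6200, upper-quartile scaling 6149, no filter 6403, the filter of at least 1 CPM in 3 libraries 6159 and limma-voom 6232; leaving out 1 library gave 5338 to 6074. Upper-quartile scaling put 43.4% of calls on the higher side against 48.8%, and 0 shared calls changed sign under any of these settings. Genes changed at least 2-fold numbered 828 to 1115 over the same settings. Without genes of the shifted stretches, 5295 genes passed, 2926 higher and 2369 lower, and 728 changed at least 2-fold.

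Of 33 lists, 8 passed with the preset correlation, 0 with an estimated correlation and 26 with fry. Fry differs by construction, since it compares no list with other genes. With an estimated correlation, camera took its p from the residual degrees of freedom of these 6 libraries, which are few. With the preset value it took them from the number of genes. So p can be larger without a higher correlation, and a higher correlation does not account for every loss. The estimate was -0.00536 for the mitotic list and -0.0337 for early differentiation, under the preset 0.01. Their unadjusted camera p still went from 2.59e-05 to 0.0101 and from 0.00495 to 0.0421. In the rest of the 8 lists the estimate was above 0.01, so both differences act there, and their shares were not separated. Leaving out 1 library gave 8 or 9 lists; the ninth, without control replicate 1, was that of mitochondrially encoded genes (adjusted p = 0.00924). Without the shifted stretches 11 lists passed, with early differentiation lost and the SREBP, simple epithelial, mitochondrially encoded and fibroblast lists gained. The mitochondrially encoded and fibroblast lists kept all their tested members (13 and 3) and their medians. Only the genes they were compared with, and the adjustment over the lists, changed. The genes left out were chosen for lower values, so this gain is no added support for a fall. Same-numbered libraries did not deviate together (correlations 0.02, -0.09 and -0.01), and not every library correlated best with its own number, so the numbers were not taken as pairs; with the replicate block 6425 genes (3155 higher, 3270 lower), 880 changed at least 2-fold and 8 lists passed. Of 190 genes followed one by one, 178 kept their direction and side of the threshold under every planned setting that gave them a value, and 0 results reversed; the other 12, CYP24A1, CD68 and MUC1 among them, crossed the threshold under at least 1. In simulated counts the test recovered 78% of 1.5-fold changes and 86% of 2-fold changes, so a gene that did not pass is not shown to be unchanged. Only 200 of 12250 simulated genes were changed, so the adjustment asked for a smaller p there than in these data. These shares are therefore not the recovery of the test on the real libraries.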

Other observations

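The chromosome patterns were found in the data before they were tested; the test of where the step on chromosome 16 lies, that of other cell types and the minimum of 20 held-out genes for a verdict were chosen after the results they measure were seen. The lists in this paragraph and the next did not pass camera with the preset correlation (smallest adjusted p = 0.0672, for mitochondrially encoded genes), and their counts adjusted over the list alone are given where they differ. Retinoid genes had 5 up and 9 down of 17 (5 and 10 adjusted over the list alone): ALDH1A3, which makes retinoic acid, rose by 0.90 and its relative ALDH1A1 changed by -3.15, the binding protein gene CRABP2, in the shifted stretch of chromosome 1, by -1.42 and the receptor gene RARG by -0.63. Cornified envelope genes had 7 up and 6 down of 16 (8 and 6 adjusted over the list alone), with CSTA at 0.87; in the shifted stretch of chromosome 1, IVL and HRNR were at -1.96 and -1.98 and SPRR1B and SPRR2A at 2.43 and 2.36; the mean and median were above 0 while fry gave a downward direction. Simple epithelial genes had 6 up and 3 down of 12, with KRT18 at 1.36 and KRT8 at 0.77. The 3 that fell, KRT19 (-1.59), ELF3 (-0.57) and MUC1 (-1.16, not past the threshold without control replicate 3 or knockout replicate 3), lie in shifted stretches. Without the genes of such stretches, an alternative chosen after seeing the data, the median went from 0.19 to 0.63 and the adjusted camera p from 0.130 to 3.25e-05. With an estimated correlation and all 12 members the adjusted camera p was 0.612. The stretches were chosen for lower values and hold 6 of the 12 members, so leaving them out favours a rise. Mesenchymal genes had 4 up and 8 down of 13, with FN1 at 1.01 and ITGA5 at 1.05 against TNC at -1.45 and S100A4, in the shifted stretch of chromosome 1, at -1.73. WNT genes had 5 up and 5 down of 14; WNT5A had 38, 48 and 24 counts in the control libraries and 0, 0 and 2 in the knockout libraries, SFRP1 changed by -2.07 and RNF43 rose by 1.49. YAP and TGF-beta targets had 10 up and 6 down of 20, with ID1 and ID3 at -1.10 and -1.23 and TGFBR1 at 0.81.

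Interferon response genes had 5 up and 8 down of 21, led by OASL (-1.54), CMPK2 (-1.59) and RSAD2 (-1.43), while OAS3 rose by 0.28. In the amino acid and unfolded protein list 6 rose and 8 fell of 23 (6 and 9 adjusted over the list alone); the transporter subunit genes SLC3A2 and SLC7A5 changed by -1.10 and -1.55, and SLC7A5 lies between SDR42E1 and the end of chromosome 16. DNA replication genes had 4 up and 6 down of 22; of the falls, CDC6 (-0.67), GINS2 (-0.79) and CDT1 (-0.88) lie in shifted stretches, while UHRF1 rose by 0.62. The p53 targets had 6 up and 7 down of 20 (6 and 8 adjusted over the list alone), with GADD45A at 1.62 and AEN at 1.08 against BTG2 at -0.71 and PHLDA3 at -0.35, both in the shifted stretch of chromosome 1, a median of -0.11 and a mean of 0.03. NRF2 genes had 6 up and 6 down of 20 (6 and 7 adjusted over the list alone), with AKR1B10 at -2.46 and SRXN1 at 0.36. Aryl hydrocarbon receptor targets had 3 up and 4 down of 8, with CYP1A1 at 2.18 and UGT1A6 at -0.64. Barrier sphingolipid genes had 8 up and 9 down of 23 (9 and 9 adjusted over the list alone), with UGCG at 0.60 and CERS4 at -2.42; desmosome and adherens junction genes had 4 up and 6 down of 18 (4 and 8 adjusted over the list alone), with NECTIN4, in the shifted stretch of chromosome 1, at -0.84 and PERP at 0.43. Calcium and phosphate genes had 9 up and 7 down of 17, with SLC20A1 at 1.61 and TRPV6 at -1.75, a median of 0.17 and a mean of -0.66. Sterol efflux genes had 2 up and 2 down of 8 (median 0.06, mean -0.03), with NR1H3 at -1.22 and SMPDL3A at 0.85, and drug transporters 0 up and 5 down of 12, with ABCC4 at -0.35. Mitochondrially encoded genes had 0 up and 7 down of 13, and their share of counts was 0.353 ± 0.00836% in knockout and 0.423 ± 0.0364% in control libraries (SD, n = 3).

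On chromosome 16, genes from SDR42E1 to the end of the long arm were lower in the knockout. Genes elsewhere matched on GC content, transcript length and expression had a median log2 fold change of 0.0761 (95% interval 0.03 to 0.11), and the highest of the 3 knockout library medians over the stretch was -0.68, so neither those properties nor 1 outlying library accounts for it. A candidate explanation is lower DNA dosage of the stretch in the knockout cells: held-out genes of low expression there lay -0.62 from held-out genes elsewhere, but these were 4 genes, too few to decide. The fitted step lay 1 gene from SDR42E1, and 2.11% of possible boundaries on the arm lie as near, yet the bootstrap interval of the step runs from 75.1 to 83.8 Mb, and at the far end of that uncertainty 18.9% lie as near, so a step there by chance stays open. RNA counts cannot tell a loss that began at the edited site from one that arose in a selected cell, in the control line or by coordinated lower transcription, nor how much of the lower SDR42E1 RNA belongs to the edit.

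Genes of chromosome 1 from 121.2 Mb and of chromosome 17 up to EZH1 were lower as well, away from the edited gene. There 133 held-out genes were available, of which 75.9% were below 0 against 64.9% of 1415 held-out genes elsewhere, and their median lay -0.37 from that of held-out genes elsewhere (95% interval -0.58 to -0.17), as lower DNA dosage predicts. Matched genes elsewhere had a median of 0.0487 (interval 0.04 to 0.06), which argues against GC content, length or expression level. These values are consistent with knockout and control cells that differ in copy number of several regions, a hypothesis that DNA from both cultures would test; a shared regulator of these regions was not tested. If it holds, part of the lower TOP2A, KRT13 and MED1 RNA may belong to dosage and not to SDR42E1.

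The wound, MAPK and AP-1, and NF-kB lists were higher in the knockout with camera's preset correlation and did not pass with an estimated correlation (adjusted p = 0.181, 0.181 and 0.251). Of their members that rose, 2 of 14, 0 of 14 and 0 of 12 lie in shifted stretches; the smallest ratio of a list's median without the stretches to its median with them was 1, which decides nothing, since all 6 stretches were lower in the knockout and the MAPK and AP-1 list has no member in them. Of 35 fibroblast, melanocyte, leukocyte and endothelial markers, 27 were under the count filter. The 8 tested had a median log2 fold change of -0.54, with 0 rises and 3 falls. VWF, 1 of the 3, did not pass with DESeq2, with no filter, or when a library other than control replicate 1 was left out. These values argue against more cells of these types in the knockout cultures, as far as 8 markers can show. They do not bear on other epithelial cells. The most abundant in knockout libraries were MITF at 19.2 ± 2.60 CPM, FBLN1 at 10.4 ± 0.124 CPM and CD68 at 8.18 ± 0.120 CPM. CD68, in a shifted stretch of chromosome 17, had a log2 fold change of 0.38 (adjusted p = 0.0695). Its values were 0.51 and 0.0393 without control replicate 2, and 0.21 and 0.345 without control replicate 1. CDH5 (-0.48) lies in a shifted stretch of chromosome 16. Loss of SDR42E1, the state of the cultures at harvest and differences between a selected clone and its parent line may each raise the wound, AP-1 and NF-kB lists. None of these was tested.

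Only 10 splits of the 6 libraries into groups of 3 exist, too few for a share under 0.05. The real split gave 6197 changed genes and was itself the only 1 of the 10 to reach that number. The highest of the others gave 1. Every other split mixes control and knockout libraries, so their difference widens the spread within its groups. Low counts there were built in and decide nothing.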
